A study of Drosophila melanogaster with 20 samples.

How the data were processed

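Small RNA libraries were made from fractions of Drosophila embryo cells sorted on a neural marker. The 20 libraries formed 10 groups of 2, and the labels call the 2 libraries of a group biological duplicates. The groups were the marker-positive and marker-negative fractions of repo and elav sorts at 6-8 h and 18-22 h after egg laying, and of a pros sort at 6-8 h. Per the labels, repo-positive fractions were enriched for glia, elav-positive fractions for neurons and pros-positive fractions for neuroblasts. Cells had been fixed in formaldehyde, stained with antibodies and separated by flow cytometry, and the libraries were read as single 51 bp reads.

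The deposited tables held 1 column of values per library over 17559 annotated features. Per the file headers the values were expected counts: featureCounts 1.5.1 had shared each read that mapped to several places among those places (fractional counting), and had assigned a read to every feature it overlapped on the same strand of the Ensembl release 85 exons. The submitters' processing notes name Bowtie 1.1.2 for mapping, SAMtools 1.8, featureCounts 1.5.1 and DESeq2 without a version. The builds named in the notes were BDGP6 and dm6. The mapping directory in the file header differed for the pros libraries from that of the others, so a difference between the pros libraries and the others may hold a difference in processing. The test had been chosen for counts, but the deposited values were estimated: 44.7% of the miRNA values and 78.1% of all values were not whole numbers. The values were therefore rounded to whole numbers before the count models. The authors also deposited 11 tables of gene and miRNA pairs with a log2 fold change and a p-value for each member, whose direction the headers do not state. It was read as second group over first, from the signs of the miRNA changes here. The gene libraries behind those tables were not among these samples, and every pair in them had opposite signs.

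Features were named with the Ensembl release 115 gene table, which held 17253 of the identifiers, while 306 were absent. A total of 237 features were miRNA hairpins, 235 named by the gene table and 2 by the authors' tables alone. Values are per hairpin and do not separate the arms. Reads on a hairpin were also counted for a host exon on the same strand, and 73 hairpins shared an exon with another gene. Near-identical hairpins (mir-6-1, mir-6-2 and mir-6-3, mir-2a-1 and mir-2a-2, mir-2b-1 and mir-2b-2, mir-13b-1 and mir-13b-2, mir-281-1 and mir-281-2, mir-31a and mir-31b, mir-276a and mir-276b, mir-92a and mir-92b) shared reads to an unknown extent, so the members of such a group are not independent. For 14 hairpins all 20 libraries held 0 counts, mir-274 and mir-285 among them. No feature matched mir-228.

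The tests of miRNAs were made with the quasi-likelihood model of edgeR 4.0.16 over all 20 libraries and 10 groups, with TMM factors from the miRNA features, the filterByExpr filter (149 miRNAs tested) and the Benjamini-Hochberg correction within each comparison at 0.05. The common biological coefficient of variation was 0.515 with 10 residual degrees of freedom. The comparisons were 5 of positive against negative fractions, 6 between positive fractions and 4 differences between such contrasts (stage or marker). Errors of log2 fold changes are standard errors of the fit, and errors of CPM are standard deviations of 2 libraries. CPM are TMM-scaled and relative to the miRNA counts of a library. A fold against a group with 0 counts is given as a lower bound, from a floor of 3 counts over the group. With 1 to 3 counts the ratio of counts is given with its 95% interval. These floors, these intervals and the intervals of library shares cover counting error only.

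The groups of miRNAs were 12 fixed lists, tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 where at least 3 members were tested, and again with an estimated correlation. Fragments of other genes in the same libraries (11731 genes tested, after leaving out 59 features that overlapped a hairpin on the same strand) were tested with the same edgeR model and fixed lists of cell-type genes. They are short fragments from size-selected libraries of fixed cells and stand for no measured mRNA level. The miRNAs named in the text were those past the correction with no overlap between the libraries of the groups and a mean of at least 10 CPM in the higher group, ranked by fold change: up to 10 per direction between positive and negative fractions and up to 6 per direction elsewhere. Both libraries of the higher group therefore lay above both of the lower group for each of them. Members of the lists, the 5 most abundant miRNAs and the sort markers were named in addition. Chosen after their values were seen were mir-252 in the elav and pros sorts, mir-1017 in the pros sort and the miRNAs named between negative fractions. The design, the lists, the naming rule and all alternatives except the added ones were chosen before the data were examined.

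Alternatives were RLE factors, scaling to the total miRNA count, library size and TMM from all features, scaling without the 5 most abundant miRNAs, no filter, a mean of at least 50 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block (5 residual degrees of freedom), fits of the 2 compared groups alone, a minimum fold of 2, leaving out each library, camera with an estimated correlation, fry, correction over the list alone, and library shares without rRNA and tRNA in the denominator. Added after the data were seen were a fit without both elav 6-8 h replicate 2 libraries, the comparisons with pros-positive cells after subtracting the difference of the negative fractions, and 4 scalings of the ratios of repo-positive to elav-positive cells. With 2 libraries per group no rule for deviating libraries was applied.

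Total counts per library ranged from 6863042 to 24501421 and miRNA counts from 70156 to 8825221. A floor of 3 counts was 22.6 CPM in elav-positive 6-8 h replicate 2, 13.0 CPM in elav-negative 6-8 h replicate 2 and 0.519 to 3.76 CPM in the other libraries. The model was tested on simulated data made from these libraries, with 42 miRNAs changed in each of 10 sets per comparison. Over the 5 positive against negative comparisons, 5.7 to 10% of 2-fold, 36.4 to 44.3% of 4-fold and 72.1 to 77.1% of 16-fold changes were found, and 1.2 to 8.2% of calls were false. For gene fragments, 11.8 to 19.1% of 4-fold and 38.2 to 54.4% of 16-fold changes were found. Most 2-fold differences would therefore be missed, and an absent call is no evidence of equal levels. Tables and figures were made with R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.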

Results

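By the mean over the 20 libraries the most abundant hairpins were mir-184 (330050 CPM), mir-7 (116770), mir-286 (97168), mir-1 (82295) and mir-5 (75260), an order that differed between groups. These 5 together held 44.5 to 76.5% of the miRNA counts of a library. Counts on miRNAs ranged from 70156 in elav-positive 6-8 h replicate 2 (1.01% of its counts, 95% interval 1.01 to 1.02%) to 8825221 in pros-positive replicate 2 (41.4%). Features of rRNA took 19.0 to 54.2% and snoRNA 5.46 to 29.3% of the counts. The log2 CPM of the 2 libraries of a group had a correlation of 0.819 in elav-positive and 0.911 in elav-negative cells at 6-8 h, and of 0.952 to 0.986 in the other 8 groups.

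**Figure D1:**
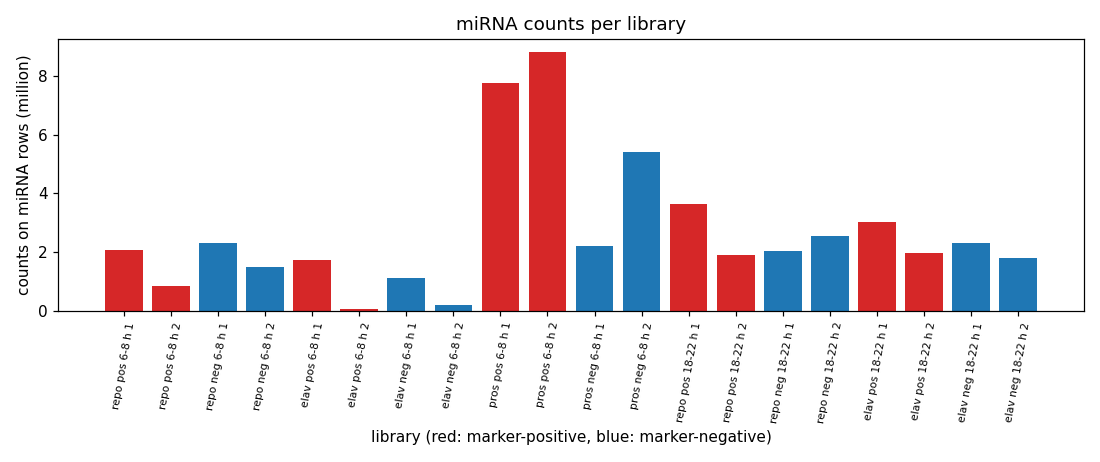
Counts on miRNA hairpins in each of the 20 libraries. The replicate 2 libraries of the elav sort at 6-8 h held 70156 (positive) and 199947 (negative).

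Fragments of the genes used for sorting were higher in each positive fraction. Fragments of repo were at 222 ± 17.8 CPM in repo-positive and 4.93 ± 0.276 CPM in repo-negative cells at 6-8 h (log2 fold change 5.49 ± 0.40, adjusted p = 1.07e-07, n = 2 libraries per group, edgeR). At 18-22 h they were at 131 ± 0.548 and 2.99 ± 0.248 CPM (5.44 ± 0.41, adjusted p = 1.3e-07). Fragments of elav were higher in elav-positive cells at 6-8 h (3.51 ± 0.35, adjusted p = 2.45e-06) and at 18-22 h (3.37 ± 0.35, adjusted p = 2.77e-06). Those of pros were higher in pros-positive cells (4.05 ± 0.38, adjusted p = 4.91e-06). The pros-positive cells also held more elav fragments than the pros-negative cells (3.23 ± 0.35, adjusted p = 2.37e-05). The elav-positive cells held more repo fragments at 6-8 h (1.32 ± 0.36, adjusted p = 0.0229) and more pros fragments at 18-22 h (1.29 ± 0.35, adjusted p = 0.0139). Fragments of elav did not pass the test in the repo sort at 6-8 h (0.36, adjusted p = 0.645). The call of repo in the elav sort ended without replicate 1 of either fraction. That of pros ended without elav-positive replicate 1 or elav-negative replicate 2 of 18-22 h.

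Neuron, glia and neuroblast genes followed these sorts among the gene fragments. All 12 neuron genes were higher in elav-positive cells at both stages (camera adjusted p = 7.24e-18 and 1.19e-21, or 0.00918 and 0.0066 with an estimated correlation). Appl was higher by 6.60 ± 0.72 and fne by 5.65 ± 0.49 at 6-8 h, and nSyb by 6.27 ± 0.71 at 18-22 h. In repo-positive cells at 6-8 h, 4 of the 12 were higher (8 adjusted over the list alone; camera adjusted p = 6.01e-05, or 0.183 with an estimated correlation). Among them were Syt1 (2.35 ± 0.63) and brp (1.61 ± 0.38, adjusted p = 0.018). Of 10 glia genes, 9 were higher in repo-positive cells at 6-8 h and 7 at 18-22 h (10 and 9 adjusted over the list alone; camera with an estimated correlation, adjusted p = 0.00262 and 0.00156). They included moody (3.31 ± 0.59) and wrapper (4.63 ± 0.98) at 6-8 h and Gli (3.33 ± 0.45) and nrv2 (3.29 ± 0.43) at 18-22 h. Of 9 neuroblast genes, 7 were higher in pros-positive cells (8 adjusted over the list alone; camera adjusted p = 1.25e-13, or 0.000659 with an estimated correlation). Among them were ase (5.56 ± 0.95), scrt (4.15 ± 0.44) and wor (3.13 ± 0.59). In pros-positive cells 6 of the 12 neuron genes were higher too (9 adjusted over the list alone; camera adjusted p = 2.94e-08, or 0.053 with an estimated correlation). The neuron calls of the repo sort at 6-8 h ended without either repo-negative library. Those of fne and brp ended without repo-positive replicate 1, and all but brp without replicate 2 (1.33 to 2.96). That of wrapper ended without repo-positive replicate 2 or either repo-negative library (adjusted p from 0.0552 to 0.145) and that of moody without repo-negative replicate 1 (0.0827). In the pros sort those of ase, wor, sna, insc and mira ended without pros-negative replicate 1 (1.68 to 5.14). The neuron calls of futsch, nrv3 and brp in that sort ended there too (1.32 to 2.85). That of nSyb ended without pros-negative replicate 2 (2.16) or pros-positive replicate 1 (2.06).

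The hairpin mir-252 (FBgn0262323) lies on 3R at 13464219 to 13464311, on the minus strand, in an exon shared with asRNA:CR17025. The hairpin mir-87 (FBgn0262428) lies on 2L at 9950418 to 9950516, on the minus strand. Other hairpins named often below were mir-927 (X, 15965947 to 15966038, minus strand, within mmd) and mir-7 (2R, 20606067 to 20606154, plus strand, within HnRNP-K). With them were mir-263b (3L, 15843406 to 15843495, minus strand, within meru) and mir-1 (2L, 20487441 to 20487531, plus strand, in an exon shared with lncRNA:CR45361). Fold changes are relative to the TMM scaling of the miRNA counts. Other scalings shifted the log2 fold change of each tested miRNA. The median of these shifts in the 11 comparisons was -0.565 to 0.362 (RLE) and -0.997 to 1.36 (total miRNA count). The median shifts were -0.527 to 0.741 (without the 5 most abundant) and -1.461 to 1.279 (all features). No miRNA named by rank of fold change took the other sign under any of them. With TMM from all features, 0 miRNAs were called by edgeR in 7 of the 11 comparisons (1 to 32 at an unadjusted p under 0.05) and 11, 1, 1 and 1 in the others, against 9 to 63 by the scaling used here.

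In repo-positive cells at 6-8 h, the glia-enriched fraction, mir-252 was at 2575 ± 171 CPM against 25.9 ± 1.87 CPM in repo-negative cells (log2 fold change 6.63 ± 0.53, adjusted p = 5.22e-08, n = 2 libraries per group, edgeR). Also higher were mir-137 (5.52 ± 1.04, adjusted p = 0.000849), mir-219 (4.13 ± 0.94, adjusted p = 0.00281) and mir-87 (4.12 ± 0.36, adjusted p = 1.14e-07). So were mir-278 (3.55 ± 0.71), mir-284 (3.40 ± 0.71), mir-276b (3.37 ± 0.41) and mir-993 (3.20 ± 0.60). The intronic hairpin mir-1017 had 42 counts in the positive and 1 in the negative libraries (ratio 65.0, 95% interval 11.1 to 2630, adjusted p = 0.00281). With 31 counts against 0 mir-2492 was higher too (adjusted p = 0.0358). Hairpins depleted from these cells were the muscle miRNA mir-1 (12883 ± 13338 against 98521 ± 15162 CPM, -2.94 ± 0.75, adjusted p = 0.00674) and mir-9a, which limits sensory organ precursors in flies (-2.34 ± 0.40, adjusted p = 0.000512). Further lower hairpins were mir-3 (-2.29 ± 0.57), mir-9c (-1.88 ± 0.50), mir-283 (-1.50 ± 0.31), mir-5 (-1.49 ± 0.35) and mir-312 (-1.35 ± 0.27). In all, 36 of 149 miRNAs passed the test, 23 higher and 13 lower. The split became 19 and 20 with RLE factors, 22 and 24 with DESeq2 and 23 and 35 without both elav 6-8 h replicate 2 libraries. Leaving out repo-negative replicate 1 or 2 gave 21 or 23 calls. Calls that ended were, without repo-positive replicate 1, mir-3 and mir-9c, and without repo-positive replicate 2, mir-1 (-2.14, adjusted p = 0.0637), mir-5, mir-9c and mir-2492. Without repo-negative replicate 1 they were mir-219, mir-1017 and mir-2492, and without repo-negative replicate 2, mir-9c and mir-2492 (adjusted p from 0.0522 to 0.165).

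Of the 11 nervous system miRNAs tested, 6 were higher in repo-positive cells at 6-8 h and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.0114, or 0.0622 with an estimated correlation). They were mir-137, mir-190 (2.14 ± 0.47), mir-219, mir-315 (2.76 ± 0.50), mir-927 (2.69 ± 0.50) and mir-932 (2.95 ± 0.87). The conserved neuronal miRNA mir-124 did not pass (0.41, adjusted p = 0.549). Of 7 widely expressed miRNAs, 5 were higher (camera adjusted p = 0.00466, or 0.0598 with an estimated correlation): mir-276a, mir-276b, mir-14, mir-184 (1.72 ± 0.47) and mir-ban, the growth-promoting bantam (1.59 ± 0.36). Of 9 sensory organ and neural precursor miRNAs, mir-263b (2.47 ± 0.55), mir-996 (2.16 ± 0.55) and mir-279 (1.25 ± 0.28) were higher and mir-9a, mir-9b and mir-9c lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.339). Lower members were 2 of 8 in the early zygotic cluster (camera adjusted p = 0.00466, or 0.299 with an estimated correlation). They were 3 of 5 in the mir-310 cluster (0.0114, or 0.167 with an estimated correlation) and 2 of 5 epithelial and gut miRNAs (0.0373, or 0.23 with an estimated correlation). The K-box family had 0 calls (edgeR, 2 at an unadjusted p under 0.05, 0 with DESeq2; 0.132), and of the 2 muscle miRNAs mir-1 was lower. Among these members calls ended for mir-190 (without replicate 1 of either fraction), mir-932 (repo-positive replicate 1, repo-negative replicate 2) and mir-184 (all but repo-positive replicate 2). They ended too for mir-996 (either repo-negative library), mir-ban (repo-negative replicate 1), mir-9b (all but repo-positive replicate 1) and mir-31a and mir-31b (each of the 4), at adjusted p from 0.0522 to 0.249.

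At 18-22 h mir-252 was the only hairpin called in the repo sort in every fit that left out 1 library. It was at 1652 ± 137 CPM in repo-positive against 132 ± 11.2 CPM in repo-negative cells (3.65 ± 0.45, adjusted p = 4.11e-05, n = 2 libraries per group, edgeR). With all libraries mir-276a (1.82 ± 0.35, adjusted p = 0.00495), mir-ban (1.58 ± 0.36, adjusted p = 0.0185) and mir-279 (1.06 ± 0.28, adjusted p = 0.0334) were higher too. Lower were mir-31a (-1.42 ± 0.35), mir-31b (-1.43 ± 0.35), mir-8 (-1.26 ± 0.35), mir-283 (-1.14 ± 0.31) and mir-312 (-0.96 ± 0.26). These were 9 calls, 4 higher and 5 lower. The split became 3 and 8 with RLE factors, 3 and 0 without the 5 most abundant miRNAs, 4 and 13 with DESeq2 and 6 and 12 without both elav 6-8 h replicate 2 libraries. Calls numbered 1 without repo-positive replicate 1 or 2 or repo-negative replicate 2 and 3 without repo-negative replicate 1, and the others ended at adjusted p from 0.0552 to 0.52.

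None of the 11 nervous system miRNAs was called in the repo sort at 18-22 h (edgeR, 0 at an unadjusted p under 0.05, 0 with DESeq2; camera adjusted p = 0.916). The epithelial and gut list had 3 of 5 members lower (mir-8, mir-31a and mir-31b; camera adjusted p = 0.000917, and 0.0483 with an estimated correlation). The widely expressed list had 2 of 7 higher (mir-276a and mir-ban; 0.000971, and 0.0282 with an estimated correlation). The K-box family had 0 calls (edgeR, 2 at an unadjusted p under 0.05, 0 with DESeq2), with a camera adjusted p of 0.00151, or 0.237 with an estimated correlation. Of the other lists, mir-279 was the 1 higher sensory and precursor miRNA (1 and 2 adjusted over the list alone; camera adjusted p = 0.745) and mir-312 the 1 lower member of the mir-310 cluster (0.606). The early zygotic cluster (1 lower adjusted over the list alone; camera adjusted p = 0.906) and the muscle list had 0 calls by edgeR, each with 1 at an unadjusted p under 0.05, and 2 and 1 by DESeq2.

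Elav-positive cells at 6-8 h, the neuron-enriched fraction, held mir-87 at 1218 ± 257 CPM against 18.5 ± 1.60 CPM in elav-negative cells (6.00 ± 0.42, adjusted p = 6.84e-09, n = 2 libraries per group, edgeR). Also higher were mir-219 (5.71 ± 1.06, adjusted p = 0.000413) and mir-927 (662 ± 95.5 against 22.5 ± 23.5 CPM, 5.32 ± 0.61, adjusted p = 3.35e-06), then mir-276b (4.97 ± 0.45, adjusted p = 2.25e-07) and mir-315 (4.71 ± 0.55, adjusted p = 3.35e-06). With 1 count in the negative libraries, mir-133 had a ratio of 137 (95% interval 24.4 to 5420, adjusted p = 0.00133) and mir-137 of 113 (20.2 to 4500, adjusted p = 0.00044). With 0 counts there, mir-932 was at least 28.3-fold higher (adjusted p = 0.000389) and mir-1017 at least 16.5-fold (adjusted p = 0.00109; 5.22 and 3.05 without elav-negative replicate 1). So were mir-990, mir-929 and mir-4973 (adjusted p = 0.00764, 0.0081 and 0.0137). Lower in elav-positive cells were mir-1 (-3.20 ± 0.76, adjusted p = 0.00248), mir-9a (-2.71 ± 0.41, adjusted p = 6.99e-05), mir-312 (-2.70 ± 0.28, adjusted p = 9.78e-07), mir-5 (-2.66 ± 0.37), mir-9b (-2.54 ± 0.44) and mir-31a (-2.44 ± 0.37). Unlike in the repo sort, mir-ban (-1.50 ± 0.36) and mir-279 (-1.50 ± 0.29) were lower. Those differences between the sorts passed their own test (-3.09 ± 0.51, adjusted p = 0.000584, and -2.75 ± 0.40, adjusted p = 0.000191). There were 51 calls, 29 higher and 22 lower. The split became 39 and 15 with total-count scaling, 10 and 1 with TMM from all features and 16 and 35 without both replicate 2 libraries. Calls that ended were, without elav-negative replicate 1, mir-1 (-1.54, adjusted p = 0.0936), mir-ban (-0.99, adjusted p = 0.052), mir-929, mir-990 and mir-4973. Without elav-positive replicate 2 they were mir-929 and mir-4973, and without elav-negative replicate 2 mir-4973 (adjusted p from 0.0501 to 0.334).

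Of the 11 nervous system miRNAs, 9 were higher and 0 lower in elav-positive cells at 6-8 h (camera adjusted p = 2.97e-05, and 0.00477 with an estimated correlation). They included mir-190 (3.26 ± 0.50), mir-1000 (3.61 ± 0.80) and mir-124 (1.88 ± 0.49, adjusted p = 0.00526). In the muscle list of 2, mir-133 was higher and mir-1 lower. Of 5 epithelial and gut miRNAs, mir-8, mir-31a and mir-31b were lower (camera adjusted p = 0.00544, or 0.146 with an estimated correlation). So were mir-3, mir-5 and mir-286 of 8 early zygotic miRNAs (0.00716, or 0.47 with an estimated correlation) and mir-311 and mir-312 of 5 in the mir-310 cluster (0.0394, or 0.283 with an estimated correlation). Among 9 sensory and precursor miRNAs 1 was higher (mir-263b, 2.87 ± 0.56) and 4 lower (camera adjusted p = 0.177). Among 7 widely expressed 3 were higher and 1 lower (0.599), and among 9 K-box miRNAs mir-13a and mir-13b-1 were higher (0.33). Calls ended for mir-124 and mir-13b-1 without elav-positive replicate 1 (1.19, adjusted p = 0.116, and 0.64, adjusted p = 0.483) and for mir-1000 without elav-positive replicate 2 (1.85, adjusted p = 0.0554). That of mir-3 ended without elav-negative replicate 1 (-1.37, adjusted p = 0.0857) and that of mir-13b-1 without elav-negative replicate 2 (1.02, adjusted p = 0.16).

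At 18-22 h the elav sort gave the most calls, 63 of 149. In elav-positive cells mir-87 was at 4422 ± 1189 CPM, against 324 ± 10.5 CPM in elav-negative cells (3.77 ± 0.35, adjusted p = 2.98e-07, n = 2 libraries per group, edgeR). Also higher were mir-932 (4.24 ± 0.87, adjusted p = 0.000952), mir-927 (4.07 ± 0.52, adjusted p = 1.18e-05) and mir-133 (3.69 ± 0.92, adjusted p = 0.0042). So was mir-7, which acts in sensory organ and photoreceptor development (104390 ± 30794 against 19202 ± 2084 CPM, 2.44 ± 0.54, adjusted p = 0.00134). From 3 counts in the negative libraries mir-957 had a ratio of 66.8 (95% interval 22.7 to 325, adjusted p = 0.00531). Lower hairpins were mir-980 (-4.91 ± 1.47), mir-3 (-3.65 ± 0.62) and mir-277 (-3.33 ± 0.58, adjusted p = 0.000188). So were mir-31a (3223 ± 674 against 29946 ± 3992 CPM, -3.22 ± 0.38, adjusted p = 5.07e-06), mir-312 (-3.04 ± 0.28, adjusted p = 2.98e-07) and mir-286 (-3.01 ± 0.39). Also lower were mir-1 (-2.76 ± 0.74, adjusted p = 0.00652), mir-ban (-2.53 ± 0.37, adjusted p = 3.46e-05) and mir-279 (-2.13 ± 0.29). So was mir-252 (99.8 ± 2.19 against 245 ± 58.4 CPM, -1.30 ± 0.42, adjusted p = 0.0196), whereas mir-252 had been higher in elav-positive cells at 6-8 h (1.65 ± 0.49, adjusted p = 0.0133). That difference between the stages was -2.95 ± 0.65 (adjusted p = 0.0217). The split of 32 higher and 31 lower became 44 and 17 with total-count scaling, 39 and 19 without the 5 most abundant miRNAs and 42 and 27 without both elav 6-8 h replicate 2 libraries. Leaving out elav-negative replicate 1 gave 35 calls and ended those of mir-957, mir-133, mir-980 and mir-252. Without elav-positive replicate 1 or 2 those of mir-1 (-2.04 and -2.31, adjusted p = 0.162 and 0.117), mir-252 (-0.73 and -0.69, adjusted p = 0.345 and 0.358) and mir-980 ended. At 6-8 h that of mir-252 ended without replicate 1 of either fraction (1.01 and 1.03; adjusted p from 0.0613 to 0.358 over all these).

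Of the 11 nervous system miRNAs, 10 were higher in elav-positive cells at 18-22 h, all but mir-929 (camera adjusted p = 1.36e-05, and 0.00364 with an estimated correlation). They included mir-219 (3.26 ± 0.85), mir-315 (3.09 ± 0.50), mir-137 (2.75 ± 0.82) and mir-124 (2.54 ± 0.49). All 5 epithelial and gut miRNAs were lower (camera adjusted p = 0.00346, or 0.111 with an estimated correlation). Lower members were 3 of 8 in the early zygotic (camera adjusted p = 0.0805) and 3 of 5 in the mir-310 cluster (0.0707), and 4 of 9 K-box miRNAs were higher (0.14). The muscle list was divided as at 6-8 h, with mir-133 higher and mir-1 lower. Of the sensory and precursor list 2 were higher and 3 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.31). Of the widely expressed list 1 was higher and 3 lower (0.408), where 1 call changed sign with total-count scaling. Without elav-negative replicate 1 the calls of mir-219 and mir-137 ended (adjusted p = 0.0613), and that of mir-137 without elav-negative replicate 2 (0.104).

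**Figure D2:**
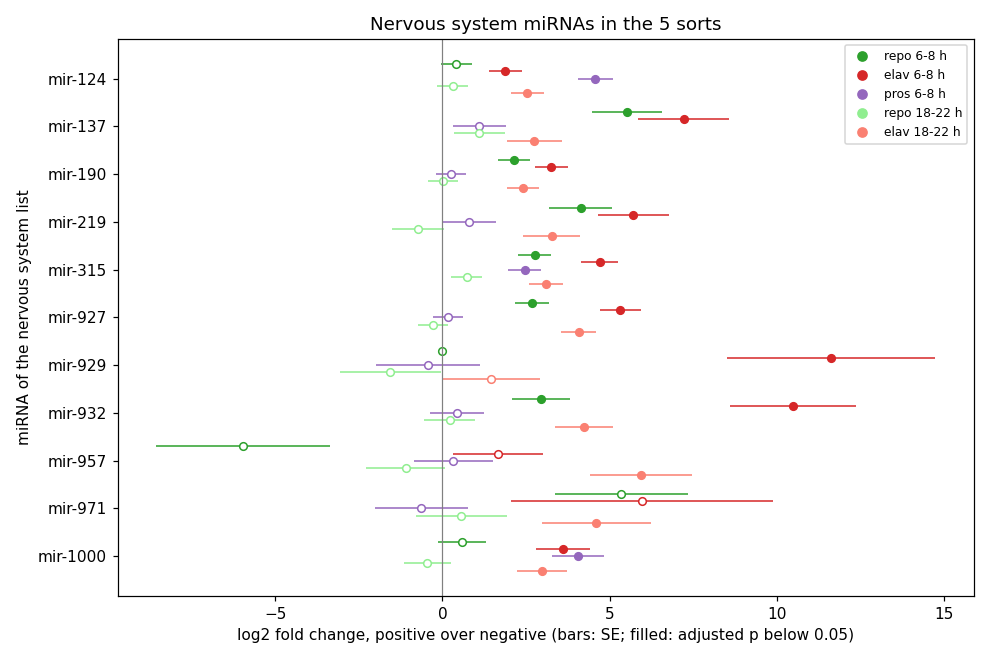
Fold changes of the 11 nervous system miRNAs between positive and negative fractions in the 5 sorts, on the log2 scale with standard errors, filled where the adjusted p was below 0.05. The fitted values of mir-929 and mir-932 in the elav sort at 6-8 h stand against 0 counts in the negative fraction and depend on the prior count.

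The pros-positive cells, enriched for neuroblasts, held mir-87 at 2948 ± 161 CPM against 84.7 ± 7.80 CPM in pros-negative cells (5.12 ± 0.37, adjusted p = 1.35e-08, n = 2 libraries per group, edgeR). There mir-263b, which protects sensory bristle cells, was at 108420 ± 6075 against 4100 ± 1164 CPM (4.72 ± 0.60, adjusted p = 2.19e-05). The neuronal mir-124 was at 442 ± 190 against 18.4 ± 2.92 CPM (4.58 ± 0.53, adjusted p = 8.9e-06). Also higher was mir-7, at 496900 ± 176020 against 105840 ± 6565 CPM (2.23 ± 0.53, adjusted p = 0.0106). Also higher were mir-1000 (4.05 ± 0.79), mir-981 (3.48 ± 0.91), mir-2c (2.85 ± 0.44) and mir-315 (2.45 ± 0.49). With lower folds there followed mir-bft, the hairpin of mir-263a (2.34 ± 0.53), mir-284 (2.08 ± 0.66, adjusted p = 0.0469) and mir-252 (1.56 ± 0.42, adjusted p = 0.0195). Lower were mir-1017 (0 against 20 counts, 17 of them in pros-negative replicate 2, adjusted p = 0.0176), and mir-31a and mir-31b (-1.21 ± 0.35, adjusted p = 0.0297). The muscle miRNA mir-1 did not differ past the test (188780 ± 88755 against 179130 ± 10039 CPM, adjusted p = 0.992). The 19 calls were 16 higher and 3 lower. The split became 7 and 6 with RLE factors, 7 and 7 with total-count scaling, 7 and 5 without the 5 most abundant miRNAs, 10 and 13 with DESeq2 and 9 and 49 without both elav 6-8 h replicate 2 libraries. Calls numbered 8 without either pros-positive library, 10 without pros-negative replicate 1 and 4 without pros-negative replicate 2. The calls of mir-981, mir-284, mir-31a and mir-31b ended without any 1 of the 4. Those of mir-252 and mir-1017 ended without pros-positive replicate 1 or pros-negative replicate 2, and that of mir-1017 also without pros-positive replicate 2. That of mir-7 ended without pros-positive replicate 2 or either negative library (adjusted p = 0.0837, 0.115 and 0.104). Those of mir-1000, mir-315 and mir-bft ended without pros-negative replicate 2.

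In pros-positive cells, 3 of 11 nervous system miRNAs were higher (mir-124, mir-315 and mir-1000; camera adjusted p = 0.229) and 3 of 9 sensory and precursor miRNAs (mir-7, mir-bft and mir-263b; 0.477). Of 5 epithelial and gut miRNAs, mir-31a and mir-31b were lower (camera adjusted p = 0.0272, or 0.281 with an estimated correlation). The K-box family had 1 higher member (mir-2c, 0.833) and the widely expressed list 1 (mir-276b, 0.477, a call that ended without any 1 of the 4 libraries, at adjusted p from 0.0756 to 0.134). The early zygotic cluster (camera adjusted p = 0.477), the mir-310 cluster (0.833) and the 2 muscle miRNAs had 0 calls by edgeR, with 1, 0 and 0 at an unadjusted p under 0.05 and 2, 0 and 0 by DESeq2.

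Calls were shared between sorts that had no library in common. Of the hairpins higher in repo-positive and in elav-positive cells at 6-8 h, 16 were the same, where 4.5 would be shared by chance, and of the lower ones 12 against 1.9. In the elav sort 22 higher (6.2 by chance) and 19 lower (4.6 by chance) hairpins were shared by the 2 stages. At 18-22 h the repo and elav sorts shared 0 higher hairpins (0.9 by chance; edgeR) and 5 lower (1 by chance).

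**Figure D3:**
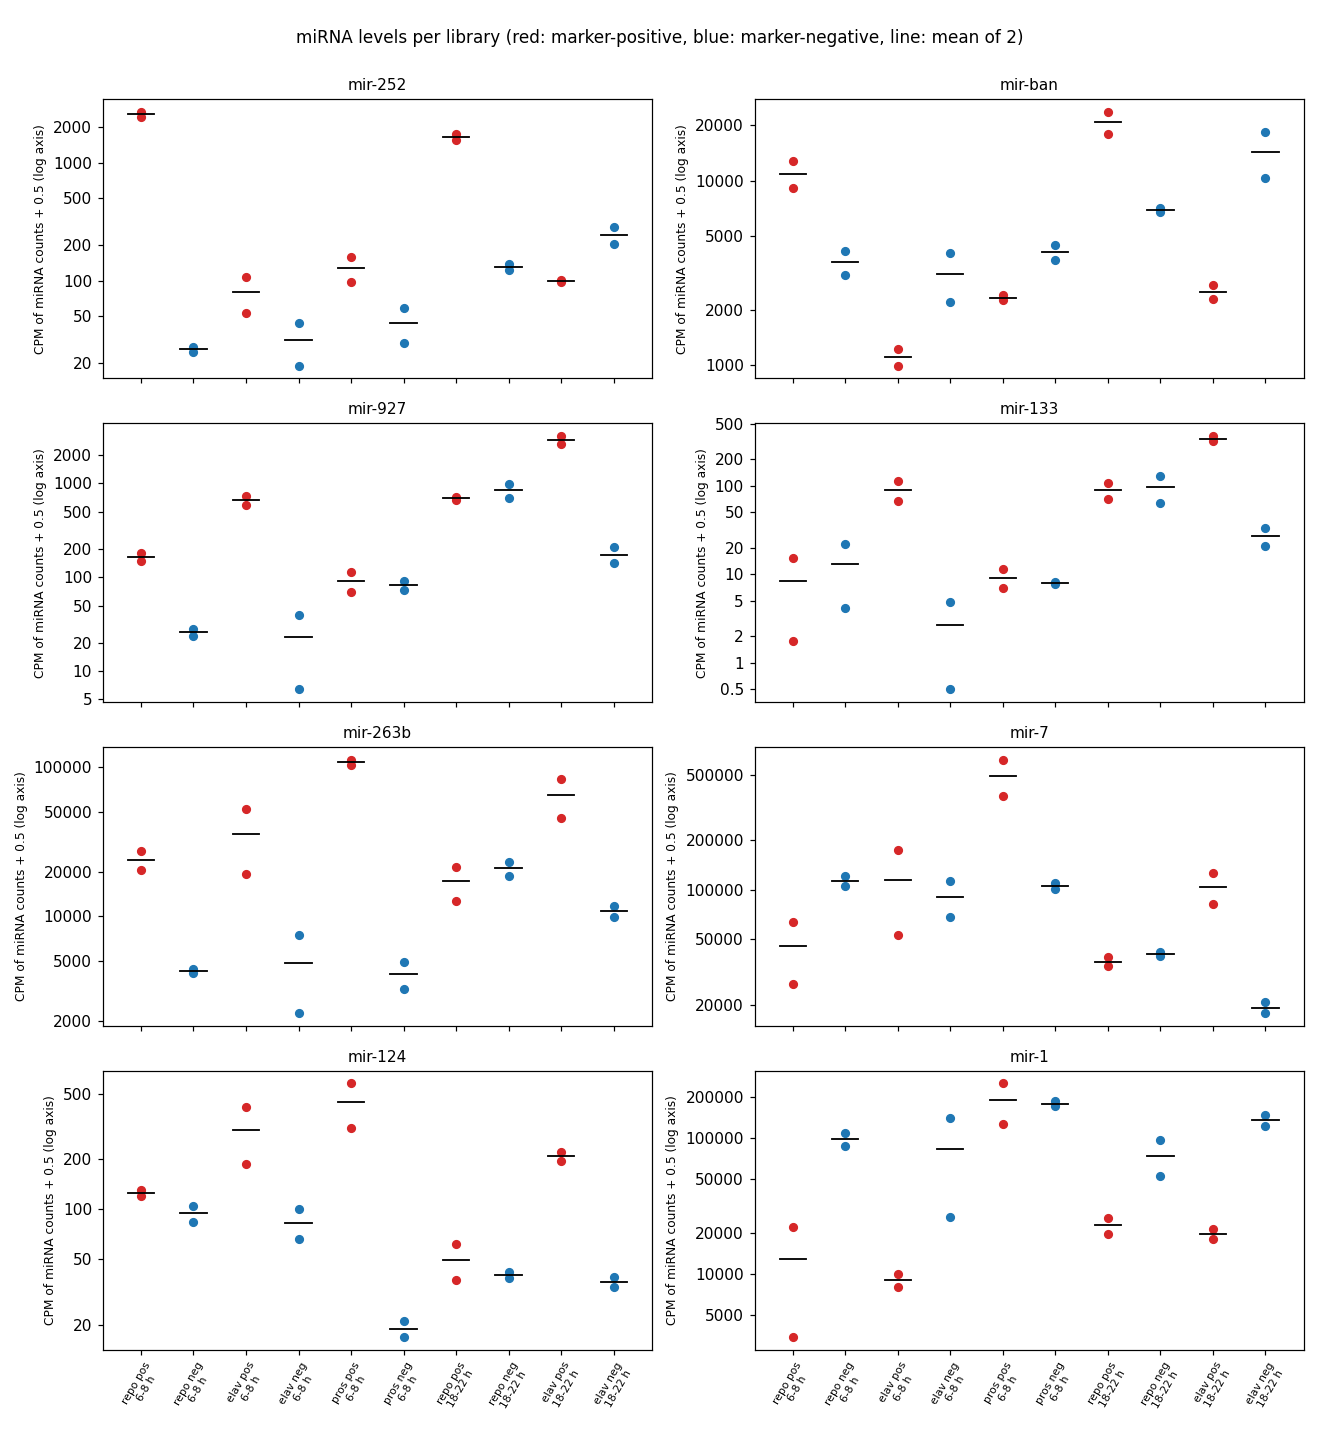
Levels of 8 miRNAs in each library, as CPM plus 0.5 on a log axis, with red points for positive and blue points for negative fractions and a line at the mean of 2 libraries.

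Set directly against elav-positive cells at 6-8 h, repo-positive cells held more mir-252 (4.89 ± 0.49, adjusted p = 1.7e-06, n = 2 libraries per group, edgeR), mir-ban (3.30 ± 0.39, adjusted p = 6.09e-06), mir-996 (3.06 ± 0.58, adjusted p = 0.0017) and mir-279 (2.89 ± 0.30, adjusted p = 1.7e-06). They also held more mir-184 (2.15 ± 0.48) and mir-286 (1.95 ± 0.37). They held less mir-1000 (-3.60 ± 0.77), mir-133 (-3.42 ± 0.95), mir-927 (-2.02 ± 0.48) and mir-190 (-1.46 ± 0.46). With 0 counts in repo-positive cells mir-929 was at least 21.3-fold lower (adjusted p = 0.0104; 7.43 without repo-positive replicate 1), and mir-957 had 66 counts, all in elav-positive replicate 1 (adjusted p = 0.0243). At 18-22 h mir-252 (4.05 ± 0.46, adjusted p = 1.23e-05), mir-ban (3.06 ± 0.38) and mir-279 (2.33 ± 0.29, both adjusted p = 1.42e-05) were again higher, with mir-286 (2.15 ± 0.38). Lower were mir-87 (-2.11 ± 0.33, adjusted p = 0.000184), mir-124 (-2.09 ± 0.48) and mir-927 (-2.07 ± 0.47). Calls numbered 17 (10 higher, 7 lower) at 6-8 h and 16 (10 and 6) at 18-22 h. The split at 6-8 h became 10 and 16 with RLE factors, 5 and 28 with total-count scaling, 9 and 14 without the 5 most abundant miRNAs and 11 and 24 with DESeq2. That at 18-22 h became 6 and 24 with total-count scaling, 5 and 10 without the 5 most abundant, 11 and 14 with DESeq2 and 11 and 23 without both elav 6-8 h replicate 2 libraries. At 6-8 h, leaving out elav-positive replicate 1 gave 32 calls and ended those of mir-184 (0.98, adjusted p = 0.188) and mir-957 (0.00, adjusted p = 1.0), and leaving out elav-positive replicate 2 those of mir-286 and mir-929. Without repo-positive replicate 1 the calls of mir-929, mir-957 and mir-927 ended, and without repo-positive replicate 2 those of mir-929, mir-957, mir-1000, mir-133 and mir-190 (adjusted p from 0.0528 to 1.0). At 18-22 h, calls numbered 8 and 6 without repo-positive replicate 1 and 2 and 6 and 8 without elav-positive replicate 1 and 2. There mir-124 lost its call without repo-positive replicate 1, mir-927 without either repo-positive library and mir-286 without elav-positive replicate 1 (adjusted p from 0.0515 to 0.292).

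Of the nervous system list, 5 of 11 members were lower at 6-8 h and 2 at 18-22 h in repo-positive than in elav-positive cells (7 and 6 adjusted over the list alone; camera adjusted p = 0.000666 and 6.95e-05, and 0.0158 and 0.00648 with an estimated correlation). The widely expressed list had 3 of 7 higher at each stage (adjusted over the list alone, 6 at 6-8 h, and 4 with 1 lower at 18-22 h; camera adjusted p = 0.00251 and 0.0423, and 0.0224 and 0.103 with an estimated correlation). Its median at 6-8 h turned to -0.12 with total-count scaling. Early zygotic members mir-286 and mir-5 were higher at both stages (camera adjusted p = 0.0359 at 6-8 h, 0.553 with an estimated correlation and 0.0588 by fry; 0.0581 at 18-22 h). The median of that list at 6-8 h turned to -0.38 under total-count scaling. Of the epithelial and gut list 0 were called at either stage (edgeR, 2 and 0 at an unadjusted p under 0.05, 0 with DESeq2). At 6-8 h 2 were higher when adjusted over the list alone (camera adjusted p = 0.0359 and 0.22, the first 0.26 with an estimated correlation), and the median turned to -0.34 under total-count scaling. Sensory and precursor calls were 3 higher at 6-8 h (3 and 2 adjusted over the list alone; camera adjusted p = 0.343) and 2 higher and 1 lower at 18-22 h (2 and 2; 0.587). The mir-310 cluster had mir-312 higher at each stage (2 and 1 adjusted over the list alone at 6-8 h; camera adjusted p = 0.39 and 0.128). The K-box family had 0 calls at 6-8 h (edgeR, 0 at an unadjusted p under 0.05, 1 with DESeq2; 0.896) and 1 lower at 18-22 h (mir-2c, 0.934). Of the muscle list mir-133 was lower at 6-8 h, with 0 calls at 18-22 h (edgeR, 1 at an unadjusted p under 0.05, 0 with DESeq2). Calls ended for mir-5 at 6-8 h without any library but repo-positive replicate 2 and at 18-22 h without any but repo-positive replicate 1. They ended for mir-312 without elav-positive replicate 1 at 6-8 h and without any but repo-positive replicate 1 at 18-22 h, and for mir-2c without any 1 of the 4 (adjusted p from 0.0737 to 0.281).

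Against pros-positive cells at 6-8 h, repo-positive cells held more mir-252 (4.33 ± 0.47, adjusted p = 5.48e-06, n = 2 libraries per group, edgeR), mir-996 (2.72 ± 0.56), mir-ban (2.23 ± 0.37) and mir-184 (2.18 ± 0.48). They held less mir-1 (-3.87 ± 0.78, adjusted p = 0.00181), mir-7 (-3.46 ± 0.56, adjusted p = 0.000471), mir-bft (-3.22 ± 0.55, adjusted p = 0.000471), as well as mir-263b (-2.17 ± 0.54) and mir-4 (-2.01 ± 0.43). With 42 against 0 counts mir-1017 was at least 63.8-fold higher (adjusted p = 0.000471; 28.0 without repo-positive replicate 2). In elav-positive against pros-positive cells mir-1017 was at least 138-fold (61.7 without pros-positive replicate 1), mir-4973 at least 74.2-fold (adjusted p = 0.00411) and mir-125 at least 14.1-fold higher (adjusted p = 0.0119; 12.1 and 5.38 without elav-positive replicate 2). Also higher was mir-219 (4.48 ± 0.90, adjusted p = 0.00102), while mir-1 (-4.39 ± 0.80, adjusted p = 0.000412), mir-31a and mir-277 (-2.74 and -2.67) were lower. Calls numbered 39 (21 higher, 18 lower) for repo and 51 (23 and 28) for elav. The repo split became 28 and 12 with total-count scaling. The elav split became 28 and 18 with RLE factors, 50 and 5 with total-count scaling, 26 and 19 without the 5 most abundant miRNAs and 33 and 19 with DESeq2. Without pros-positive replicate 2 the counts were 19 and 30. The call of mir-263b ended without repo-positive replicate 1 (adjusted p from 0.051 to 0.244 over all such calls). That of mir-277 ended without elav-positive replicate 1, and that of mir-125 without elav-positive replicate 2 or either pros-positive library (adjusted p from 0.0575 to 0.172). The pros libraries may also differ from the others in processing, and after subtracting the difference of the negative fractions 18 and 25 calls were left.

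In these comparisons with pros-positive cells, 3 nervous system miRNAs of 11 were higher and 1 lower in repo-positive cells (3 and 2 adjusted over the list alone; camera adjusted p = 0.561). In elav-positive cells 7 were higher (0.00163, and 0.0234 with an estimated correlation). The K-box family had 5 of 9 higher in each, with mir-2c lower (6 and 1 adjusted over the list alone for repo; camera adjusted p = 0.0173 and 0.0104, or 0.316 and 0.272 with an estimated correlation). In the elav comparison 1 of these calls changed sign with total-count scaling. Of 9 sensory and precursor miRNAs 5 were lower and 2 higher for repo (camera adjusted p = 0.081), and 7 lower for elav (0.00362, or 0.105 with an estimated correlation). Epithelial and gut miRNAs had 2 and 3 of 5 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.0799 and 0.00405, the latter 0.105 with an estimated correlation). There 1 elav call changed sign with total-count scaling. Early zygotic miRNAs had 2 and 3 of 8 lower (0.119 and 0.00405, the latter 0.272 with an estimated correlation). The mir-310 cluster had 2 and 3 of 5 lower (0.0799 and 0.0271, the latter 0.218 with an estimated correlation). Widely expressed miRNAs had 5 of 7 higher for repo (0.0173, or 0.121 with an estimated correlation). For elav 1 was higher and 2 lower (0.769), where both lower calls changed sign with total-count scaling. In the muscle list mir-1 was lower in both and mir-133 higher in elav-positive cells. The call of mir-133 ended without pros-positive replicate 2 (3.08, adjusted p = 0.0817). That of mir-2c ended without pros-positive replicate 2 in both (-0.77 and -0.26, adjusted p = 0.203 and 0.692) or without either elav-positive library (adjusted p = 0.643 and 0.176). The value of mir-8 turned to 0.03 in elav-positive cells without elav-positive replicate 1 (adjusted p = 0.967).

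From 6-8 h to 18-22 h, repo-positive cells gained mir-956 (5.06 ± 0.92, adjusted p = 0.000516, n = 2 libraries per group, edgeR), mir-277, which acts on amino acid catabolism (4.47 ± 0.65, adjusted p = 9.52e-05), mir-133 (3.37 ± 0.94) and mir-375 (2.47 ± 0.47). They lost mir-3 (-4.78 ± 0.66, adjusted p = 6.08e-05), mir-275 (-3.00 ± 0.34, adjusted p = 6.43e-06), mir-312 (-2.60 ± 0.28, adjusted p = 4.71e-06) and mir-92b (-2.29). In elav-positive cells mir-277 (3.43 ± 0.72, adjusted p = 0.00248), mir-956 (3.38), mir-278 (2.85) and mir-31a (2.52 ± 0.37, adjusted p = 9.39e-05) rose. There mir-3 (-4.10 ± 0.65, adjusted p = 0.000169), mir-310 (-3.00 ± 0.41), mir-275 (-2.40) and mir-let7 (-5.93 ± 1.76, adjusted p = 0.0209) fell. Calls numbered 28 (14 higher, 14 lower) in repo-positive and 31 (16 and 15) in elav-positive cells. The repo split became 23 and 11 with RLE factors, 17 and 11 with total-count scaling, 16 and 10 without the 5 most abundant miRNAs, 27 and 15 with DESeq2 and 28 and 17 without both elav 6-8 h replicate 2 libraries. The elav split became 23 and 11 without the 5 most abundant and 32 and 13 without those libraries. Leaving out repo-positive 18-22 h replicate 1 or 2 gave 14 or 18 calls, and elav-positive 18-22 h replicate 1 or 2 gave 13 or 15. The call of mir-133 in repo-positive cells ended without 6-8 h replicate 2 or 18-22 h replicate 1 (adjusted p from 0.064 to 0.303). In elav-positive cells that of mir-let7 ended without 6-8 h replicate 2 (-1.15, adjusted p = 0.674) or either 18-22 h library. That of mir-956 ended without 6-8 h replicate 1 or either 18-22 h library (adjusted p from 0.0611 to 0.674).

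All 5 epithelial and gut miRNAs were higher at 18-22 h in both repo-positive and elav-positive cells (camera adjusted p = 0.000568 and 0.000237, or 0.086 and 0.0605 with an estimated correlation). The early zygotic cluster, whose members act on maternal mRNA, had mir-3, mir-5 and mir-286 of 8 lower in both (0.0101 and 0.00353, or 0.489 and 0.354). The mir-310 cluster had 3 of 5 lower in repo-positive and 4 in elav-positive cells (0.00849 and 0.000549, or 0.143 and 0.0605 with an estimated correlation). Nervous system miRNAs had 2 of 11 higher in repo-positive (mir-927 and mir-957; 2 and 1 adjusted over the list alone) and 1 in elav-positive cells (mir-927; camera adjusted p = 0.0702 and 0.0554). Widely expressed miRNAs had 2 of 7 lower in repo-positive cells (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.993). In elav-positive cells 3 were higher and 2 lower (4 and 2; 0.835). Of the sensory and precursor list mir-996 was lower in repo-positive cells (0.428) and 0 were called in elav-positive cells (edgeR, 1 at an unadjusted p under 0.05, 1 with DESeq2; 0.835). The K-box family had 0 calls in both (edgeR, 0 at an unadjusted p under 0.05, 0 with DESeq2; 0.442 and 0.585), and of the muscle list mir-133 was higher in repo-positive cells. The muscle list had 0 calls in elav-positive cells (edgeR, 1 at an unadjusted p under 0.05, 0 with DESeq2). Calls ended for mir-8 and mir-957 in repo-positive cells without any 1 of the 4 libraries. They ended for mir-5 and mir-996 without any but 6-8 h replicate 2, and for mir-286 without either 18-22 h library (adjusted p from 0.0596 to 0.287). In elav-positive cells they ended for mir-286 without either 18-22 h library, for mir-5 without any but 6-8 h replicate 1 and for mir-8 without any but 6-8 h replicate 2 (adjusted p from 0.0663 to 0.339).

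Among the remaining lists, mir-iab-4 of 3 Hox cluster miRNAs was higher in repo-positive than in pros-positive cells (1.82; camera adjusted p = 0.746). Of the 3 members of the let-7 complex, which acts at metamorphosis, mir-125 was the 1 call in elav-positive against pros-positive cells (2 adjusted over the list alone; 0.424). Both mir-125 (ratio of 1 to 11 counts 0.0333, 95% interval 0.000773 to 0.229, adjusted p = 0.042) and mir-let7 were lower in elav-positive cells at 18-22 h than at 6-8 h (camera adjusted p = 0.278). Both calls ended without elav-positive 6-8 h replicate 2 (adjusted p = 0.43 and 0.674) or either 18-22 h library (adjusted p from 0.138 to 0.191). The call of mir-125 against pros-positive cells ended without elav-positive replicate 2 or either pros-positive library (adjusted p from 0.0603 to 0.115), and that of mir-iab-4 without repo-positive replicate 2 or either pros-positive library (0.0695 to 0.147). In the other comparisons the let-7 complex, the Hox miRNAs and the 8 testis cluster miRNAs had 0 calls by edgeR, with 5, 3 and 4 at an unadjusted p under 0.05 and 5, 1 and 0 by DESeq2. Their camera adjusted p ranged from 0.22 to 0.893, from 0.373 to 0.827 and from 0.191 to 0.931. Adjusted over the list alone, 1 member of the let-7 complex was higher in repo-positive against pros-positive cells and 1 Hox miRNA in the pros sort. None of the glial list could be tested.

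The difference between positive and negative fractions changed with stage for 10 miRNAs in the repo sort, all smaller at 18-22 h. They included mir-87 at -4.36 ± 0.47 (adjusted p = 4.93e-06, n = 2 libraries per group, edgeR), mir-252 at -2.98 ± 0.60 and mir-927 at -2.97 ± 0.68. It changed for 2 in the elav sort, mir-252 and mir-87 (-2.23 ± 0.49, adjusted p = 0.0217). Between the elav and repo sorts it differed for 11 miRNAs at 6-8 h, with mir-252 at -4.98 ± 0.67 (adjusted p = 0.000138). At 18-22 h it differed for 31, where mir-252, mir-ban, mir-279 and mir-87 had an adjusted p of 1.27e-05 and mir-927 of 0.00016. The splits were 0 higher and 10 lower, 0 and 2, 3 and 8, and 16 and 15. The first became 5 and 12 with DESeq2 and 12 and 13 without both elav 6-8 h replicate 2 libraries. The second became 1 and 3 with RLE factors, 1 and 5 with DESeq2 and 8 and 1 without those libraries. The third became 4 and 5 with RLE factors, 12 and 10 with DESeq2 and 7 and 10 without those libraries, and the last 32 and 11 without those libraries.

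Leaving out 1 library moved these 4 counts. The 10 of the repo sort became 4 and 3 without repo-negative 6-8 h replicate 1 and 2, and 1 and 1 without repo-positive 18-22 h replicate 1 and 2. They became 3 without repo-negative 18-22 h replicate 1, while mir-87 kept its call. Of mir-252 it ended without either repo-positive 18-22 h library (adjusted p = 0.0611 and 0.135). Of mir-927 it ended without either repo-negative 6-8 h library, repo-negative 18-22 h replicate 1 or either repo-positive 18-22 h library (0.0509 to 0.245). The 2 of the elav sort became 19 without elav-positive 6-8 h replicate 1 and 4 without each of the other 6-8 h libraries. They became 0 without either elav-positive library or elav-negative replicate 1 of 18-22 h (edgeR, 15 to 19 at an unadjusted p under 0.05) and 1 without elav-negative replicate 2 of 18-22 h. The miRNAs mir-252 and mir-87 each lost the call in 6 of 8 fits (edgeR, adjusted p from 0.0581 to 0.482). The 11 at 6-8 h became 4 and 7 without repo-positive replicate 1 and 2, 4 without either repo-negative library and 18 without elav-positive replicate 1. The 31 at 18-22 h became 17 and 14 without repo-positive replicate 1 and 2, 10 without repo-negative replicate 1, 19 without elav-positive replicate 1 and 9 without elav-negative replicate 1. In both, mir-252, mir-ban and mir-279 kept their calls.

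In the authors' deposited pair tables mir-252 had a log2 fold change of 6.29 in the repo sort at 6-8 h and 3.39 at 18-22 h. The tables listed 40, 56 and 24 miRNAs for the repo, elav and pros sorts at 6-8 h. They listed 18 and 65 for repo and elav at 18-22 h. Of these 33, 46, 14, 9 and 57 also passed the test here, out of 36, 51, 19, 9 and 63 calls. The authors' deposited fold changes for mRNA of the sort genes were 8.32 and 6.48 for repo in the repo sorts, 5.47 for pros in the pros sort and 3.92 and 3.66 for elav in the elav sorts.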

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

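The tests of explanations in this part were chosen after the results were seen, while the tests of the differences themselves had been chosen before. The results stand out because the difference between positive and negative fractions itself differed between stages or sorts (edgeR, adjusted p under 0.05). In the repo sort it was smaller at 18-22 h than at 6-8 h for mir-1017 (-5.88 ± 1.59), mir-219 (-4.86 ± 1.21), mir-137 (-4.41 ± 1.28), mir-87 (-4.36 ± 0.47), mir-278 (-3.38 ± 0.92) and mir-993 (-3.18 ± 0.80). The value of mir-1017 stands against 1 count in repo-negative cells at 6-8 h and depends on the prior count. With 1 library left out mir-87 kept its call in all 8 fits. Without repo-negative 6-8 h replicate 1, repo-negative 18-22 h replicate 1 or either repo-positive 18-22 h library the other 5 lost theirs (edgeR, adjusted p from 0.0611 to 0.271). Without repo-negative 6-8 h replicate 2 those of mir-1017, mir-219, mir-278 and mir-993 ended (0.0572 to 0.164), without repo-positive 6-8 h replicate 2 those of mir-1017, mir-137 and mir-278 (0.153), and without repo-negative 18-22 h replicate 2 those of mir-137 and mir-278 (0.0723 and 0.0635).

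In the repo sort, 10 miRNAs (these 6 with mir-252, mir-276b, mir-263b and mir-927) had a smaller difference at 18-22 h. Choosing by it favours a repo-negative rise and a repo-positive fall. From 6-8 h to 18-22 h their median change was 4.22 in repo-negative (2.28 to 7.20) and 0.39 in repo-positive cells (-0.64 to 2.09). Neuron gene fragments rose by a median of 3.68 in repo-negative cells. The 0.39 argues against a loss from repo-positive cells. Neurons carried there at 6-8 h (which the sort should remove) are a candidate source. The values argue against it for mir-252. Its log2 ratio to elav-positive cells lay at least 5.40 above those of all 12 neuron genes (elav 98.4 against 558 CPM) under 5 scalings. For the other 9 the median ratio lay 1.75 above that of the neuron genes (permutation p = 0.00043, 100000 permutations), but 0.80 above it with total-count scaling (p = 0.15), so carried neurons and expression in glia cannot be told apart. Glia may also express some of the 12 genes, and in elav-positive cells the 10 changed with stage by a median of 1.31 (1.13 to 3.17 over the scalings).

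In the elav sort the difference between fractions was smaller at 18-22 h for mir-252 (-2.95 ± 0.65) and mir-87 (-2.23 ± 0.49). Without elav-negative 6-8 h replicate 1, elav-negative 18-22 h replicate 1, elav-positive 6-8 h replicate 2 or either elav-positive 18-22 h library both calls ended (edgeR, adjusted p from 0.0602 to 0.482, mir-87 at -0.82 without elav-positive 6-8 h replicate 2). That of mir-252 ended also without elav-positive 6-8 h replicate 1 (-1.72, adjusted p = 0.151) and that of mir-87 without elav-negative 18-22 h replicate 2 (0.0581).

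At 6-8 h the difference was larger in the elav than in the repo sort for mir-133 (7.08 ± 1.72, against 1 count in elav-negative cells and dependent on the prior count), mir-927 (2.63 ± 0.77) and mir-87 (1.88 ± 0.50). It was lower, sign included, for mir-252 (-4.98 ± 0.67), mir-966 (-3.81 ± 1.08), mir-ban (-3.09 ± 0.51), mir-996 (-2.95 ± 0.79), mir-279 (-2.75 ± 0.40) and mir-184 (-2.56 ± 0.66). All but mir-252 were negative in the elav sort. Calls of mir-252, mir-ban and mir-279 were kept in all 8 fits without 1 library. That of mir-133 ended without elav-negative replicate 1 or repo-negative replicate 2 (4.89 and 5.34). Those of mir-927 and mir-996 ended without elav-negative replicate 1 or any 1 of the repo libraries (mir-927 at 1.38 without elav-negative replicate 1). That of mir-87 ended without any but elav-positive replicate 1 and repo-positive replicate 2, that of mir-966 without any but elav-negative replicate 1 and elav-positive replicate 2 (-2.12 without elav-negative replicate 2). That of mir-184 ended without elav-negative replicate 2, elav-positive replicate 1 (-1.44), either repo-negative library or repo-positive replicate 1.

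At 18-22 h the difference was larger in the elav sort for mir-957 (7.05 ± 1.91, against 3 counts in elav-negative cells and dependent on the prior count), mir-927 (4.35 ± 0.67), mir-932 (4.03 ± 1.11), mir-87 (4.01 ± 0.46), mir-219 (3.99 ± 1.14) and mir-133 (3.79 ± 1.21). It was lower, sign included, for mir-252 (-4.94 ± 0.61), mir-ban (-4.11 ± 0.52), mir-279 (-3.19 ± 0.40), mir-286 (-3.12 ± 0.52), mir-277 (-2.66 ± 0.77) and mir-184 (-2.64 ± 0.67). These were negative in the elav sort. Calls of mir-927, mir-87, mir-252, mir-ban, mir-279 and mir-286 were kept in all 8 fits. Without elav-negative replicate 1 those of mir-957, mir-932, mir-219, mir-133, mir-277 and mir-184 ended, and without repo-positive replicate 2 the same 6. Without repo-negative replicate 1 all of these but mir-184 ended, without repo-positive replicate 1 mir-957, mir-932, mir-133 and mir-277, and without elav-negative replicate 2 mir-957, mir-219 and mir-133. Without either elav-positive library mir-277 and mir-184 ended, and without repo-negative replicate 2 mir-277.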

How the results depend on the processing

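The fit without both elav 6-8 h replicate 2 libraries and the subtraction of the negative fractions were tests chosen after the results were seen. Calls are given in this order: repo, elav and pros sorts at 6-8 h, repo and elav sorts at 18-22 h, repo and elav against pros, repo against elav at 6-8 h and 18-22 h, and the stages in repo-positive and elav-positive cells. These were 36, 51, 19, 9, 63, 39, 51, 17, 16, 28 and 31, and the 4 differences of such contrasts 10, 2, 11 and 31. A setting not named below moved a count by no more than 1.5 times, and no miRNA named by rank of fold change took the other sign in any of them. Where a library was left out, the lone library of its group was assumed to vary like the other groups.

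With library size and TMM from all features the 11 counts were 0, 11, 0, 0, 0, 0, 1, 0, 0, 1 and 1 (edgeR; for the counts of 0, 17, 9, 1, 32, 32, 11 and 2 at an unadjusted p under 0.05). Without both elav 6-8 h replicate 2 libraries the repo sort at 6-8 h gave 58, the pros sort 58, the repo sort at 18-22 h 18, repo against elav 29 and 34, the stages in repo-positive cells 45, and the first 3 differences 25, 9 and 17. The calls of gene fragments in the elav sort at 6-8 h fell to 212 there. Fits of the 2 compared groups alone gave 21 in the elav sort at 6-8 h, 36 in the pros sort, 20 in the repo sort at 18-22 h, 0 for elav against pros, 11 and 46 for repo against elav, and 0 for the stages in elav-positive cells (edgeR, 37 and 24 at an unadjusted p under 0.05 for the counts of 0). Without the 5 most abundant miRNAs the pros sort gave 12 and the repo sort at 18-22 h 3. With no filter the repo sort at 18-22 h gave 1, repo against elav at 18-22 h 9, and the elav difference between stages 0 (edgeR, 20 at an unadjusted p under 0.05). DESeq2 gave 17 in the repo sort at 18-22 h, 35 and 25 for repo against elav, and 17, 6 and 22 for the first 3 differences. Among gene fragments it gave 806 (repo, 6-8 h), 673 (pros) and 450 (repo, 18-22 h), against 398, 290 and 275. RLE factors gave 26 for repo against elav at 6-8 h and 3 and 4 for the first 2 differences. Scaling to the total miRNA count gave 33 and 30, and limma-voom 33 at 18-22 h, for repo against elav. After subtracting the negative fractions 18 and 25 calls were left against pros. The cause of these shifts was not tested, except that the fits of 2 groups had 2 residual degrees of freedom.

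With the replicate blocks the repo sort at 18-22 h gave 15 calls and the first 3 differences 18, 9 and 19, and no other count moved by over 1.5 times. The labels do not say that a number marks a shared sort. The deviations of same-numbered libraries had correlations of 0.083 (repo), 0.273 (elav) and -0.164 (pros) at 6-8 h and 0.297 (repo) and 0.054 (elav) at 18-22 h, so the numbers were not taken as pairs.

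Leaving out 1 library gave 21 to 30, 42 to 56, 4 to 10, 1 to 3, 35 to 44, 19 to 29, 30 to 59, 12 to 32, 6 to 8, 14 to 22 and 13 to 42 calls in the 11 comparisons. The 4 differences gave 1 to 11, 0 to 19, 4 to 18 and 9 to 29. Among gene fragments the calls were 76 to 402, 445 to 1159, 54 to 789, 64 to 132 and 795 to 1109 in the 5 sorts, against 398, 1051, 290, 275 and 1675.

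With an estimated correlation the camera test of 27 of 35 list results of the 11 comparisons lost its call. The adjusted p was then 0.0622 for the nervous system list (repo, 6-8 h) and 0.105 for the sensory and precursor list (elav against pros). For epithelial and gut miRNAs it was 0.23, 0.146, 0.281 and 0.111 (repo, elav and pros at 6-8 h, elav at 18-22 h), 0.105 (elav against pros), 0.26 (repo against elav, 6-8 h) and 0.086 and 0.0605 (stages). For the early zygotic cluster it was 0.299, 0.47, 0.272, 0.553, 0.489 and 0.354, in the same order where called, and fry gave 0.0588 for repo against elav at 6-8 h. For the mir-310 cluster it was 0.167, 0.283, 0.218, 0.143 and 0.0605, for the K-box family 0.237 (repo, 18-22 h), 0.316 and 0.272 (repo and elav against pros), and for widely expressed miRNAs 0.0598 (repo, 6-8 h), 0.121 (repo against pros) and 0.103 (repo against elav, 18-22 h). The other 8 kept it.

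Without rRNA, tRNA and the features that overlapped a hairpin, miRNAs held 1.97 to 72.6% of a library. The fewest miRNA counts were in the elav sort at 6-8 h, where a floor of 3 counts stood at 22.6 CPM in elav-positive replicate 2.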

Other observations

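The tests of explanations in the last 2 paragraphs were chosen after the results were seen, and the gene lists had been fixed before. All 5 hemocyte genes tested were lower in elav-positive cells at 18-22 h (camera adjusted p = 8.2e-05, and 0.0406 with an estimated correlation), and 3 in repo-positive cells at 18-22 h (4 adjusted over the list alone; 4.04e-06, and 0.0126 with an estimated correlation). At 6-8 h 3 were lower in elav-positive cells (0.019, or 0.165 with an estimated correlation), 1 in repo-positive (2 adjusted over the list alone; 0.167) and 1 in pros-positive cells (0.0799). Pxn, which encodes peroxidasin, fell in all 5 sorts (repo -3.30 ± 0.69, elav -3.56 ± 0.65 and pros -4.31 ± 0.68 at 6-8 h, repo -4.42 ± 0.62 and elav -4.29 ± 0.62 at 18-22 h). The phagocytic receptor gene NimC1 was at 0.492 ± 0.00877 CPM in elav-positive against 17.3 ± 4.30 CPM in elav-negative cells at 18-22 h (-5.10 ± 0.87, adjusted p = 0.000347, n = 2 libraries per group, edgeR). The call of Pxn in the repo sort at 6-8 h ended without either repo-positive library or repo-negative replicate 2. Calls of srp and NimC1 in the repo sort at 18-22 h ended without any 1 of the 4 libraries. In the elav sort that of srp ended at 6-8 h without elav-positive replicate 2 and at 18-22 h without replicate 1 of either fraction. That of crq ended at 6-8 h without elav-negative replicate 2 or elav-positive replicate 1 and at 18-22 h without elav-positive replicate 2. That of Hml ended at 18-22 h without any but elav-negative replicate 2.

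Of 10 muscle and mesoderm genes, 4 were lower in elav-positive cells at 6-8 h, among them Mef2 (-2.09 ± 0.33, adjusted p = 0.00028, n = 2 libraries per group, edgeR), and 5 at 18-22 h (6 adjusted over the list alone), among them Act57B (-1.37 ± 0.30, adjusted p = 0.00301). The camera adjusted p was 0.00125 and 0.00105, or 0.131 and 0.0991 with an estimated correlation. In the repo and pros sorts at 6-8 h and the repo sort at 18-22 h 0 were called by edgeR (4, 2 and 6 at an unadjusted p under 0.05, 0, 1 and 2 by DESeq2; 0, 1 and 6 lower adjusted over the list alone). Their camera adjusted p was 0.31, 0.169 and 0.00215 (0.121 with an estimated correlation). The call of Act57B ended without elav-positive replicate 1, and those of sls, Mhc and up at 6-8 h and of sls, Mhc, up and Mlc2 at 18-22 h each ended in 2 or 3 of the 4 fits without 1 library. Neuron genes had 0 calls in the repo sort at 18-22 h (edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.0429, or 0.367 with an estimated correlation). Glia genes in the elav sort had repo higher at 6-8 h (2 higher and 1 lower adjusted over the list alone; 0.917) and nrv2 (2.10 ± 0.41) higher and loco (-1.80 ± 0.36) lower at 18-22 h (0.919). In the pros sort they had 0 calls (edgeR, 2 at an unadjusted p under 0.05, 1 by DESeq2, 1 adjusted over the list alone; 0.0213, or 0.209 with an estimated correlation). Neuroblast genes had scrt higher in elav-positive cells at 6-8 h (3.03 ± 0.42; list 0.77) and at 18-22 h (4.18 ± 0.44, with pros higher and insc lower; list 0.247). The neuroblast list had 0 calls in the repo sort at 6-8 h (edgeR, 1 at an unadjusted p under 0.05, 0 by DESeq2; 0.455), and at 18-22 h wor was lower (-3.07 ± 0.69; list 0.212). The call of wor ended without any 1 of the 4 libraries and that of insc without elav-positive replicate 2.

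Of 41 epidermis genes, 1 was higher and 1 lower in the repo sort at 6-8 h (cora 2.35 ± 0.44, grh -2.38 ± 0.48), 1 higher in it at 18-22 h (cora), and 2 and 3 lower in the elav sort at 6-8 h (1 higher and 4 lower adjusted over the list alone) and 18-22 h (1 lower). The camera adjusted p was 0.455, 0.00537, 0.715 and 0.00917, where 0.00537 and 0.00917 became 0.136 and 0.152 with an estimated correlation. The pros sort had 0 (edgeR, 13 at an unadjusted p under 0.05, 3 by DESeq2; 0.0136, or 0.149 with an estimated correlation). Of 5 gut genes GATAe was lower in the pros sort (-3.02 ± 0.65) and in both sorts at 18-22 h (0.0799, 0.779 and 0.621). The gut list had 0 calls in the repo and elav sorts at 6-8 h (edgeR, 2 and 2 at an unadjusted p under 0.05, 1 and 0 by DESeq2; 0.455 and 0.917). Of 2 trachea genes vvl was lower in repo-positive cells at 6-8 h (-1.39 ± 0.37) and higher in elav-positive cells at 18-22 h (1.77 ± 0.36). Of 4 fat body genes Adh was higher in repo-positive cells at 6-8 h (2.44 ± 0.59; 0.293), and of 3 germline genes pgc was lower in pros-positive cells and in elav-positive cells at 18-22 h (0.0558 and 0.507). These lists had 0 calls elsewhere (edgeR, at most 1 at an unadjusted p under 0.05 in a sort, 0 by DESeq2), with camera adjusted p from 0.126 to 0.983. With 1 library left out, calls ended in 2 to 4 of 4 fits for cora, grh, vvl, Adh and pgc, except vvl in the elav sort (1 fit) and grh there (0), and for GATAe in 3 of 4 in the pros sort and the repo sort at 18-22 h.

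Between the positive fractions, glia genes were higher in repo-positive than in pros-positive cells (9 of 10; camera adjusted p = 0.00944 with an estimated correlation) and than in elav-positive cells (7 at each stage; 0.00367 and 0.00331). Neuron genes were lower in repo-positive than in elav-positive cells (9 and 12 of 12; 0.00516 and 0.00331) and higher in elav-positive than in pros-positive cells (10; 0.0403). Neuroblast genes were lower than in pros-positive cells in repo-positive (7 of 9; 0.00944) and elav-positive cells (4; 0.0403). From 6-8 h to 18-22 h, muscle genes were higher (5 of 10 in each), neuroblast genes lower (5 and 3 of 9) and neuron genes higher (3 of 12 in each; 8, and 10 with 1 lower, adjusted over the list alone) in repo-positive and elav-positive cells. With an estimated correlation the camera adjusted p was 0.0638, 0.0638 and 0.0792 in repo-positive and 0.0433 for each list in elav-positive cells. Of 41 epidermis genes 1 was higher in repo-positive (7 adjusted over the list alone), and 3 higher and 1 lower in elav-positive cells (6 and 1; camera adjusted p = 0.00126 and 0.00122, or 0.0873 and 0.0733 with an estimated correlation). These comparisons of fragments were not repeated with libraries left out.

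In elav-positive cells at 6-8 h mir-let7 was at 3.86 and 181 CPM in replicates 1 and 2, mir-125 at 1.55 and 52.6 and mir-4973 at 3.48 and 369. Together they held 80 counts in replicate 2 against 1.18 expected at the rate of replicate 1 (23 counts), which argues against counting error from the few miRNA counts of replicate 2. No other explanation, technical or biological, was tested.

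The pros-negative cells at 6-8 h differed from the repo-negative cells in 7 miRNAs (16 by DESeq2), such as mir-31a (1.88 ± 0.36, adjusted p = 0.00383), and from the elav-negative cells in 12 (27 by DESeq2), such as mir-87 (2.16 ± 0.38, adjusted p = 0.00397), while repo-negative and elav-negative cells differed in 0 (edgeR, 9 at an unadjusted p under 0.05, 2 by DESeq2). An older collection for the pros sort is a candidate explanation. In elav-negative cells 32 miRNAs rose and 14 fell with stage. Their median pros-negative to repo-negative log2 ratios were 0.62 and -0.78 (difference 1.40). Permutation p here (7e-05) and above took features as independent, without library spread. For mir-1 (3.87 ± 0.78 higher in pros-positive than repo-positive cells) muscle RNA and expression in the sorted cells cannot be told apart. The sort on pros should remove muscle cells. Of the 10 muscle and mesoderm genes 3 were called higher in pros-positive cells (1.93 to 3.42) and 1 lower (-0.95). The median was -0.08 (twi -3.28, not called). The mapping directory differed with the pros sort, so processing and sort cannot be told apart. The cells each sort removed from its negative fraction stay open, untested.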
